A study of Drosophila melanogaster with 12 samples.

How the data were processed

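The table analysed holds the counts of reads per gene as deposited by the authors, 15222 genes in 12 libraries. Per the labels, RNA was depleted of ribosomal RNA with RiboZero and sequenced on an Illumina HiSeq. The submitters' processing notes name TopHat 1.3.2, Bowtie 0.12.7 and Cufflinks 1.1.0 with the genome build dm3. The tool that counted the reads and the strand of the libraries are not given in the sources used here. Columns were assigned to groups by genotype, sucrose and replicate number in the library titles, with 0 columns left over. Values are whole numbers, and the smallest chi-square per gene between 2 libraries was 4.19, so no library is a copy of another.

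The comparisons, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Alternatives covered scaling, test, filter, block, threshold, the groups fitted and the omission of each library, always 1 at a time. Replicate numbers 1 to 3 were not used as a block, because the labels do not say what they share. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 8662 of 13018 genes with any count. Of all genes, 2204 were at 0 in every library. Library sizes were scaled by TMM, and the quasi-likelihood test of edgeR 4.0.16 was fitted to all 12 libraries with 1 mean per group (common dispersion 0.107). The 4 pairwise comparisons and the interaction were each adjusted by Benjamini-Hochberg at 0.05. Levels are CPM on TMM library sizes. R 4.3.3 was used, with limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 with matplotlib 3.10.9 for figures.

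Where a group held 0 counts the fold is a bound, with 3 counts over the group in place of 0. Where it held 1 to 3 counts a ratio of summed counts with a 95% counting interval is given. That interval treats reads as independent and leaves out the spread between libraries. A floor of 3 counts was 0.423 to 3.27 CPM in a single library.

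Named genes followed a rule. For each pairwise comparison these were InR and svp, then the 10 largest rises and 10 largest falls in log2 fold change. They had to have adjusted p under 0.05, replicate values that do not overlap between the groups, and a mean of at least 5 CPM in the higher group. For each list described up to 4 members with the smallest p could be named. For the interaction the rule asked for 5 genes per direction, and none passed. Genes outside the rule were chosen after their values were seen, and this is said where they appear.

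The 34 gene lists were fixed by symbol. They cover insulin and Tor signalling, FOXO targets, fatty acid and triglyceride synthesis, lipolysis, glycolysis, sugar storage, pentose phosphate, gluconeogenesis and the tricarboxylic acid cycle. They also cover cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, immune effectors, larval serum proteins, secreted signals, heat shock proteins, endoplasmic reticulum chaperones and autophagy. The others are glutathione S-transferases, P450 genes, ecdysone response, DNA replication, nutrient transcription factors, and markers of salivary gland, muscle, midgut, hemocytes, nervous system, germline, cuticle, trachea, imaginal disc and males. camera tested 33 of them per comparison with a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated for each list. The male list had fewer than 3 genes with enough counts and was only described. Of the symbols 11541 were current, 3353 were synonyms and 328 matched no gene in a later annotation, which served for names and exonic lengths only.

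The analysis was tested on simulated data with 200 changed genes of at least 5 CPM, 100 by 2-fold and 100 by 4-fold. Counts were drawn with the library sizes, means and dispersions of these data, so the rates below assume that no library stands apart. edgeR recovered 62% to 74% of 4-fold changes in the pairwise comparisons but only 3% to 9% of 2-fold ones, with 1 to 6 unchanged genes called. For the interaction it recovered 9% of 4-fold and 0% of 2-fold changes. DESeq2 recovered 84% to 90% of 4-fold pairwise changes with 18 to 25 unchanged genes called. In 1 of these simulations (n = 12 libraries) camera gave an unadjusted p = 0.00916 for a list of unchanged genes.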

Results

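Gene expression was measured in the larval fat body of female Drosophila melanogaster at the wandering stage. This organ stores fat and glycogen and secretes most proteins of the haemolymph. Mothers carrying UAS-Dcr2 and the fat body driver r4-GAL4 were mated to control males of stock 60000 (w1118) or to males of stock 992. The latter carry UAS-InRi, an RNA interference construct against the insulin receptor gene InR. Offspring grew at 25 °C on 0.15 M or 0.7 M sucrose, which gave 4 groups of 3 libraries from total RNA depleted of ribosomal RNA. Replicates 1, 2 and 3 held 3505887, 1525455 and 3502143 counts for control 0.15 M and 6380813, 4654649 and 7114144 for InRi 0.15 M. On 0.7 M sucrose they held 4695974, 5135234 and 872755 for control and 5803618, 5136224 and 3143289 for InRi. Of 15222 genes, 8662 held enough counts to be tested with edgeR. Levels are CPM, counts scaled to a library of 1e+06 counts, as mean ± SD, n = 3, with the libraries labelled InRi, or those on 0.7 M sucrose, given before those they are compared with. All p-values measure only the spread between these libraries, because the labels do not say whether they came from separate cultures.

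InR, which encodes the insulin receptor and is the target of the construct, was higher and not lower in the libraries labelled InRi. On 0.15 M sucrose it stood at 61.1, 26.0 and 43.1 CPM in control and at 151, 133 and 116 CPM in libraries labelled InRi (log2 fold change 1.60, SE 0.30, adjusted p = 0.0185). On 0.7 M sucrose the values were 56.4, 45.4 and 55.5 CPM in control and 109, 163 and 148 CPM in libraries labelled InRi (log2 fold change 1.42, SE 0.30, adjusted p = 0.0157). Sucrose left InR with a log2 fold change of 0.25 in control (adjusted p = 0.764) and 0.07 in the libraries labelled InRi (adjusted p = 0.973). The call on 0.15 M sucrose ended without control 0.15 M replicate 3 (adjusted p = 0.0572) or InRi 0.15 M replicate 1 (0.0929). It also ended when only the 2 groups compared were fitted (adjusted p = 0.295). On 0.7 M sucrose the call ended without control 0.7 M replicate 1, 2 or 3 or InRi 0.7 M replicate 2 or 3 (adjusted p up to 0.0947). Because these counts go against the label, all directions below are those of the libraries labelled InRi, and none is read as an effect of less InR transcript.

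svp, which encodes a nuclear receptor, stood at 109 ± 33.3 against 98.8 ± 37.4 CPM on 0.15 M sucrose (adjusted p = 0.823). It rose in the libraries labelled InRi on 0.7 M sucrose (177 ± 39 against 76.3 ± 11.7 CPM, log2 fold change 1.22, SE 0.32, adjusted p = 0.0472). That call ended in 9 of 12 omissions (adjusted p up to 0.209, without control 0.7 M replicate 2). With sucrose svp had a log2 fold change of -0.37 in control (adjusted p = 0.685) and 0.70 in the libraries labelled InRi (adjusted p = 0.429). Of the male-specific RNAs, roX1 ran from 2.23 to 24.1 CPM and roX2 from 0 to 6.87 CPM, and msl-2 ran from 9.43 to 26.0 CPM.

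Mitochondrial transcripts and genes detected set control 0.15 M replicate 2 apart from the other 11. Mitochondrial genes took 0.0451% of its counts, against 0.776% to 6.67% elsewhere. In it 7628 genes were detected, against 9214 to 11312 elsewhere. Its Spearman correlation with the other libraries ran from 0.676 to 0.774, while pairs of the others ran from 0.859 to 0.974. It lay alone at the far end of the first principal component (54.9% of variance). All 12 libraries were kept, this one also in other omissions. Without it 0 of 159 named gene calls ended. Values without it are given for counts of genes, lost list calls and passing list medians moved over 1.5 times.

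**Figure D1:**
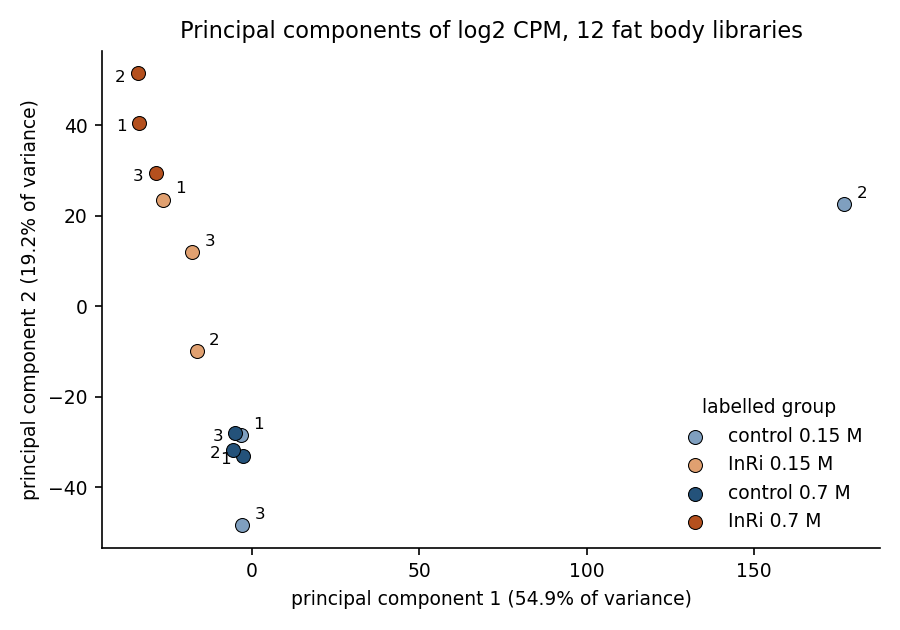
First 2 principal components of log2 CPM over the 8662 tested genes. Each point is 1 library, coloured by group and numbered by replicate.

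Turandot stress proteins and immune-induced peptides were among the largest rises in the libraries labelled InRi on 0.15 M sucrose. TotC, whose product is secreted under stress, stood at 167 ± 80.2 against 2.92 ± 3.54 CPM (log2 fold change 5.62, SE 0.75, adjusted p = 0.00427). Its relatives Victoria (119 ± 130.5 against 2.03 ± 1.73 CPM, adjusted p = 0.0138) and TotB (37.7 ± 18 against 1.09 ± 1.66 CPM, adjusted p = 0.00948) rose with it. The antifungal peptide gene Drs stood at 4258 ± 2384 against 236 ± 154 CPM (log2 fold change 4.17, SE 0.66, adjusted p = 0.00849). IM2, which encodes an immune-induced secreted peptide, stood at 225 ± 86.3 against 8.73 ± 14.6 CPM (log2 fold change 4.55, SE 0.96, adjusted p = 0.0338). CG1077, with only 3 counts in control, stood at 29.1 ± 14.3 against 0.273 ± 0.472 CPM (ratio 83.1, counting interval 28.3 to 404, adjusted p = 0.00721). CG43202, with 2 counts in control, stood at 6.98 ± 2.17 against 0.182 ± 0.315 CPM (ratio 30, counting interval 8.16 to 250.5, adjusted p = 0.015). CG43153 (102 ± 69.8 against 2.31 ± 2.32 CPM, adjusted p = 0.0042) and CG16836 (177 ± 106 against 5.45 ± 9.44 CPM, adjusted p = 0.0282) rose as well. So did CG15068 (105 ± 67.6 against 3.19 ± 5.04 CPM, adjusted p = 0.00948) and CG33462 (50 ± 21.9 against 1.57 ± 1.64 CPM, adjusted p = 0.00477). Of 31 antimicrobial and immune effector genes, 5 rose, 1 fell and 25 did not pass (15 and 1 adjusted over the list alone). The immune list had a median log2 fold change of 1.23 (camera adjusted p = 9.25e-08, or 0.693 with an estimated correlation). Among its genes PGRP-SC2, which encodes a peptidoglycan recognition protein, stood at 420.0 ± 139 against 84.5 ± 45.7 CPM (adjusted p = 0.0171). Several IM and Turandot genes are close paralogs, so single-gene values are uncertain if reads were split between copies. The log2 fold change without control 0.15 M replicate 1 was 9.01 (IM2), 7.32 (TotB) and 7.90 (CG15068), each over 1.5 times its value. CG1077, CG43202 and CG16836 then had no counts in control. The IM2 call ended in 9 of 12 omissions (adjusted p up to 0.124, without InRi 0.15 M replicate 1). CG16836 lost its call in 6 of 12 omissions (adjusted p up to 0.115, without InRi 0.15 M replicate 1). CG43202 lost its call without control 0.15 M replicate 3 or InRi 0.15 M replicate 1 (adjusted p up to 0.0621) and PGRP-SC2 without InRi 0.15 M replicate 1 (adjusted p = 0.0804).

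Yp3, Sodh-1 and GstD10 were among the largest falls in the libraries labelled InRi on 0.15 M sucrose. Yp3, a yolk protein gene, stood at 3.11 ± 2.18 against 136 ± 109.8 CPM (log2 fold change -5.44, SE 0.73, adjusted p = 0.00427). Sodh-1, which encodes a sorbitol dehydrogenase, stood at 16.3 ± 7.58 against 157 ± 73.7 CPM (log2 fold change -3.26, SE 0.52, adjusted p = 0.00895). The glutathione S-transferase gene GstD10 stood at 6.64 ± 2.39 against 65.6 ± 50 CPM (log2 fold change -3.32, SE 0.52, adjusted p = 0.00823). CG3397 (34.9 ± 21.5 against 456 ± 288 CPM, adjusted p = 0.00941) and CG8560 (3.21 ± 1.24 against 27.4 ± 5.59 CPM, adjusted p = 0.00522) fell too. The P450 gene Cyp6a2 stood at 1.19 ± 0.596 against 10.2 ± 4.94 CPM (adjusted p = 0.0179). NAAT1, an amino acid transporter gene, stood at 0.663 ± 0.188 against 6.44 ± 5.4 CPM (adjusted p = 0.0484). The glue gene Sgs1 stood at 1.44 ± 1.61 against 28.3 ± 21.6 CPM (adjusted p = 0.0185). CG34279 (4.72 ± 5.1 against 38.2 ± 6.24 CPM, adjusted p = 0.0377) and CG10592 (1.46 ± 0.899 against 11.7 ± 5.04 CPM, adjusted p = 0.0432) fell as well. Of 14 glutathione S-transferase genes, 0 rose, 2 fell and 12 did not pass (0 and 5 adjusted over the list alone). These transferases had a median log2 fold change of -0.64 (camera adjusted p = 0.00329, or 0.705 with an estimated correlation). GstD1 was among them at 107 ± 30.6 against 469 ± 123 CPM (adjusted p = 0.00688). That list lost its call without control 0.15 M replicate 3 (adjusted p = 0.253). Its median moved by over 1.5 times in 8 of 12 omissions, from -0.35 without that library to -1.33 without control 0.15 M replicate 2, when 6 of its genes fell. GstD10 lost its call without InRi 0.15 M replicate 1 (adjusted p = 0.0507). Sgs1 lost its call without InRi 0.15 M replicate 1 or 3 (adjusted p up to 0.115) and Cyp6a2 without InRi 0.15 M replicate 2 or 3 (adjusted p up to 0.0814). NAAT1 and CG10592 lost theirs in 8 of 12 omissions (adjusted p up to 0.22 and 0.209, without InRi 0.15 M replicate 1) and CG34279 in 8 of 12 omissions (adjusted p up to 0.173, without InRi 0.15 M replicate 3).

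Pentose phosphate and glycolysis lay lower as lists in the libraries labelled InRi on 0.15 M sucrose, without calls for single genes, while sugar storage (camera adjusted p = 0.329) and gluconeogenesis (0.105) did not pass. Of 7 pentose phosphate genes, 0 passed singly, while 0 rose and 6 fell adjusted over the list alone. This pathway had a median log2 fold change of -1.81 (camera adjusted p = 0.000348, or 0.693 with an estimated correlation). Pgd, a dehydrogenase gene of the pathway, stood at 60.9 ± 9.95 against 293 ± 279 CPM (adjusted p = 0.062). Of 13 glycolysis genes, 0 passed singly, while 0 rose and 2 fell adjusted over the list alone. Glycolysis had a median log2 fold change of -0.88 (camera adjusted p = 0.00329, or 0.735 with an estimated correlation). Its gene Tpi stood at 204 ± 42.5 against 1320.4 ± 1562 CPM (adjusted p = 0.0693). Of 37 tricarboxylic acid cycle and respiratory chain genes, 0 passed singly, also adjusted over the list alone. These genes had a median log2 fold change of -0.54 (camera adjusted p = 0.0143, or 0.741 with an estimated correlation). Of 72 mitochondrial ribosomal protein genes, 0 passed singly, also adjusted over the list alone. Mitochondrial ribosomal proteins had a median log2 fold change of -0.35 (camera adjusted p = 0.0054, or 0.735 with an estimated correlation). Glycolysis lost its call without control 0.15 M replicate 2 (adjusted p = 0.363). The tricarboxylic acid cycle lost it without control 0.15 M replicate 2 or InRi 0.15 M replicate 1 (adjusted p up to 0.671). Mitochondrial ribosomal proteins lost it without control 0.15 M replicate 3 (adjusted p = 0.253); their median was then -0.18. Without control 0.15 M replicate 2 the median was -0.66 for pentose phosphate, -0.24 for glycolysis and -0.08 for the tricarboxylic acid cycle, which had -0.81 without replicate 1.

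Insulin signalling and FOXO targets lay higher as lists, most genes without a call, in the libraries labelled InRi on 0.15 M sucrose. Of 11 FOXO target genes, 2 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone). FOXO targets had a median log2 fold change of 0.62 (camera adjusted p = 0.00317, or 0.693 with an estimated correlation). They included InR itself and Ilp6, which encodes the insulin-like peptide of the fat body (453 ± 180.2 against 129.6 ± 42.3 CPM, log2 fold change 1.80, SE 0.37, adjusted p = 0.0296). Of 23 insulin and Tor signalling genes, 2 rose, 0 fell and 21 did not pass (7 and 1 adjusted over the list alone). Insulin and Tor signalling had a median log2 fold change of 0.23 (camera adjusted p = 0.0351, or 0.705 with an estimated correlation). The signal gene egr, which encodes the fly tumour necrosis factor, stood at 158 ± 68.8 against 38.4 ± 16 CPM (log2 fold change 2.02, SE 0.42, adjusted p = 0.0296). The insulin list lost its call without control 0.15 M replicate 3 or InRi 0.15 M replicate 1 (adjusted p up to 0.253), and its median was 0.14 without control 0.15 M replicate 2. Ilp6 and egr lost theirs in 7 of 12 omissions (adjusted p up to 0.157 and 0.15, without InRi 0.15 M replicate 1).

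P450 and midgut genes went in both directions in the libraries labelled InRi on 0.15 M sucrose. Lsp1alpha, a larval serum protein gene, stood at 4348 ± 2069.8 against 24916 ± 9058 CPM (log2 fold change -2.52, SE 0.49, adjusted p = 0.0236). Of 61 P450 genes, 4 rose, 4 fell and 53 did not pass (6 and 10 adjusted over the list alone). Cyp4e3 (23.7 ± 4.09 against 2.23 ± 1.95 CPM, adjusted p = 0.00638) and Cyp18a1 (9.65 ± 5.67 against 0.368 ± 0.415 CPM, adjusted p = 0.00968) rose, and the product of Cyp18a1 inactivates ecdysone. Cyp9b2 fell (40.7 ± 14 against 221 ± 84.3 CPM, adjusted p = 0.0074), and the P450 list did not pass (median -0.20, camera adjusted p = 0.352). Without control 0.15 M replicate 2 it passed (-0.31, adjusted p = 0.0116, or 0.804 with an estimated correlation). Of 38 midgut marker genes, 2 rose, 2 fell and 34 did not pass (2 and 14 adjusted over the list alone). Midgut markers had a median log2 fold change of -0.95 (camera adjusted p = 2.07e-06, or 0.693 with an estimated correlation). LysC, a lysozyme gene, stood at 31.3 ± 9.95 against 5.14 ± 2.64 CPM (adjusted p = 0.00638). Mal-A6, a maltase gene, stood at 53.2 ± 23.1 against 236 ± 113 CPM (adjusted p = 0.0185). Of 9 salivary gland marker genes, 0 rose, 1 fell and 8 did not pass (0 and 2 adjusted over the list alone). Salivary gland markers had a median log2 fold change of -1.75 (camera adjusted p = 0.000348, or 0.693 with an estimated correlation). That median was -4.86 without InRi 0.15 M replicate 2, which stood apart in these genes (mean log2 CPM 5.49, against 1.69 and 2.59 in replicates 1 and 3). Lsp1alpha lost its call without control 0.15 M replicate 3, InRi 0.15 M replicate 1 or 2 or control 0.7 M replicate 1 (adjusted p up to 0.166). Mal-A6 lost its call without InRi 0.15 M replicate 1 (adjusted p = 0.0804).

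Across all genes 83 rose and 67 fell in the libraries labelled InRi on 0.15 M sucrose, 150 of 8662. At an unadjusted p under 0.05 there were 1626 genes, and DESeq2 called 560 (259 higher, 301 lower). All 150 passed again without control 0.15 M replicate 2, when 383 genes were called (174 higher, 209 lower). The count was 366 (122 higher, 244 lower) without control 0.15 M replicate 1 and 93 without replicate 3. It was 43 and 70 without InRi 0.15 M replicates 1 and 3, and 95 and 98 without control 0.7 M replicates 1 and 3. With only the 6 libraries of the comparison fitted it was 0. Of 33 lists, 10 passed with the preset correlation (3 higher, 7 lower) and 0 with an estimated one (smallest adjusted p = 0.693).

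Immune-induced peptide genes went from nearly no counts in control to high levels in the libraries labelled InRi on 0.7 M sucrose. IM2 stood at 360.0 ± 61.6 against 0.0657 ± 0.114 CPM (1 count in control, ratio 3841, counting interval 689 to 151760.0, adjusted p = 0.00142). IM1 stood at 214 ± 72.4 against 0.0738 ± 0.128 CPM (1 count, ratio 2386, counting interval 428 to 94288, adjusted p = 0.0041). IM4 stood at 187 ± 68.5 against 0.197 ± 0.341 CPM (3 counts, ratio 674, counting interval 230.2 to 3268, adjusted p = 0.00186). IM14 stood at 108 ± 30.1 against 0.205 ± 0.198 CPM (3 counts, ratio 394, counting interval 134 to 1911, adjusted p = 0.00121). CG17999 stood at 137 ± 48.3 against 0.197 ± 0.341 CPM (3 counts, ratio 506, counting interval 173 to 2457, adjusted p = 0.00199). At 0 counts in control were IM23 (50.5 ± 10.2 CPM, at least 177-fold, adjusted p = 0.00558) and CG18107 (13.4 ± 3.31 CPM, at least 46.9-fold, adjusted p = 0.00214). CG43175 was at 0 too (14.3 ± 15.1 CPM, at least 50.1-fold, adjusted p = 0.0207). IM3 stood at 1289.9 ± 426 against 3.83 ± 2.15 CPM (log2 fold change 8.55, SE 1.64, adjusted p = 0.00972) and CG15067 at 275 ± 36.7 against 0.353 ± 0.334 CPM (log2 fold change 9.11, SE 1.28, adjusted p = 0.00169). Of 31 antimicrobial and immune effector genes, 15 rose, 2 fell and 14 did not pass (24 and 2 adjusted over the list alone). Immune effectors had a median log2 fold change of 1.99 (camera adjusted p = 1.97e-18, or 0.241 with an estimated correlation). The median was the same with the gene at 0 counts set to its bound. The antifungal gene Drs stood at 4059 ± 1363 against 65.3 ± 13.8 CPM (log2 fold change 5.96, SE 0.72, adjusted p = 0.00108) and PGRP-SC2 at 575 ± 11.2 against 48 ± 17.7 CPM (adjusted p = 0.00108). The IM1 call ended without control 0.7 M replicate 2 (adjusted p = 0.0519). IM3 lost its call without control 0.7 M replicate 1 or 2 (adjusted p up to 0.0727) and CG43175 without control 0.7 M replicate 1 or 2 or InRi 0.7 M replicate 1 (adjusted p up to 0.109).

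Salivary gland glue genes and a larval serum protein gene were among the largest falls in the libraries labelled InRi on 0.7 M sucrose. Lsp1alpha, whose storage protein the fat body secretes, stood at 269.6 ± 113 against 22875 ± 1930.2 CPM (log2 fold change -6.41, SE 0.59, adjusted p = 0.00056). CG34279 stood at 0.326 ± 0.312 against 59.3 ± 16.8 CPM (log2 fold change -7.47, SE 0.94, adjusted p = 0.00108). mthl8, a gene of the methuselah-like receptors, was at 0 against 5.03 ± 1.54 CPM (at least 21.7-fold lower, adjusted p = 0.015). The glue gene Sgs3 stood at 5.84 ± 6.51 against 505 ± 124 CPM (log2 fold change -6.49, SE 1.31, adjusted p = 0.0125). Sgs7 (18 ± 21.9 against 1866 ± 943 CPM, adjusted p = 0.0162) and Sgs8 (9.39 ± 12.1 against 1013 ± 597 CPM, adjusted p = 0.0202) fell with it. Sgs5 stood at 1.51 ± 2.46 against 179.7 ± 126 CPM (adjusted p = 0.0495). Sgs1 stood at 0.163 ± 0.156 against 29.3 ± 15.2 CPM (2 counts in the libraries labelled InRi, ratio 182, counting interval 50 to 1512, adjusted p = 0.00315). CG7587 (7.29 ± 10.4 against 955 ± 750.2 CPM, adjusted p = 0.027) and CG7606 (4.58 ± 5.49 against 302 ± 161 CPM, adjusted p = 0.0148) fell too. Of 9 salivary gland marker genes, 0 rose, 7 fell and 2 did not pass (0 and 8 adjusted over the list alone). The glue list had a median log2 fold change of -6.72 (camera adjusted p = 2.99e-10, or 0.291 with an estimated correlation). The median was -6.49 with genes at 0 counts set to their bounds. Whether fat body cells transcribe these genes was not measured. Sgs7 and Sgs8 are close paralogs, so reads may have been shared. The Sgs3 call ended without control 0.7 M replicate 1 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.0745). Sgs7, Sgs8 and CG7606 lost theirs without control 0.7 M replicate 1 or 2 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.0821, 0.0948 and 0.0804). Sgs5 lost its call in 8 of 12 omissions (adjusted p up to 0.203, without InRi 0.7 M replicate 2). CG7587 lost its call without control 0.7 M replicate 1, 2 or 3 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.117). mthl8 lost its call without control 0.7 M replicate 1 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.0831).

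Insulin signalling and FOXO targets lay higher as lists, with 4 and 5 genes rising, in the libraries labelled InRi on 0.7 M sucrose. Of 11 FOXO target genes, 5 rose, 1 fell and 5 did not pass (6 and 1 adjusted over the list alone). FOXO target genes had a median log2 fold change of 1.12 (camera adjusted p = 0.000988, or 0.47 with an estimated correlation). InR itself counts in this list and in that of insulin signalling. The triglyceride lipase gene bmm stood at 197 ± 45.7 against 54 ± 6.73 CPM (log2 fold change 1.86, SE 0.33, adjusted p = 0.00588). Ilp6 stood at 662 ± 191 against 175 ± 22.2 CPM (adjusted p = 0.0103) and the activin-like ligand gene daw at 348 ± 73.1 against 151 ± 15.5 CPM (adjusted p = 0.0229). Of 23 insulin and Tor signalling genes, 4 rose, 0 fell and 19 did not pass (8 and 0 adjusted over the list alone). The signalling list had a median log2 fold change of 0.57 (camera adjusted p = 0.00182, or 0.47 with an estimated correlation). Akt1, which encodes the central kinase of the pathway, stood at 112 ± 17.2 against 51.7 ± 5.93 CPM (adjusted p = 0.0498). Of 20 nutrient and metabolic transcription factor genes, 3 rose, 0 fell and 17 did not pass (3 and 0 adjusted over the list alone). These factors had a median log2 fold change of 0.38 (camera adjusted p = 0.0175, or 0.514 with an estimated correlation). HLH106, the fly gene of the sterol regulatory element binding protein, stood at 169.9 ± 25 against 72.7 ± 14.9 CPM (adjusted p = 0.0173). The tumour necrosis factor gene egr stood at 258 ± 78.7 against 52.3 ± 10.7 CPM (log2 fold change 2.31, SE 0.42, adjusted p = 0.00771). Of 28 endoplasmic reticulum chaperone and unfolded protein response genes, 0 passed singly, also adjusted over the list alone. Chaperones had a median log2 fold change of 0.33 (camera adjusted p = 0.0153, or 0.63 with an estimated correlation). The nutrient factor list lost its call without control 0.7 M replicate 2 (adjusted p = 0.107). Chaperones lost theirs without control 0.7 M replicate 1 or InRi 0.7 M replicate 2 (adjusted p up to 0.0752). Ilp6 lost its call without control 0.7 M replicate 1 or 2 or InRi 0.7 M replicate 2 (adjusted p up to 0.0713). The daw call ended without control 0.7 M replicate 1, 2 or 3 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.116) and the egr call without control 0.7 M replicate 1 (adjusted p = 0.059). Akt1 lost its call in 10 of 12 omissions (adjusted p up to 0.203, without control 0.7 M replicate 2). HLH106 lost its call without control 0.7 M replicate 1 or 3 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.1).

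Sugar storage genes and glutathione S-transferases lay lower as lists in the libraries labelled InRi on 0.7 M sucrose, with 4 genes of each called, while P450 genes went both ways. Of 18 trehalose, glycogen and sugar transport genes, 0 rose, 4 fell and 14 did not pass (0 and 5 adjusted over the list alone). Sugar storage genes had a median log2 fold change of -0.44 (camera adjusted p = 0.0175, or 0.47 with an estimated correlation). That median was -0.23 without InRi 0.7 M replicate 2. Sodh-1 stood at 2.78 ± 2.17 against 77 ± 26.1 CPM (log2 fold change -4.88, SE 0.60, adjusted p = 0.00108). tobi, which encodes an alpha-glucosidase, stood at 4.14 ± 2.87 against 21.4 ± 5.13 CPM (log2 fold change -2.39, SE 0.48, adjusted p = 0.0123). Of 14 glutathione S-transferase genes, 0 rose, 4 fell and 10 did not pass (0 and 8 adjusted over the list alone). Glutathione S-transferases had a median log2 fold change of -0.97 (camera adjusted p = 3.13e-05, or 0.491 with an estimated correlation). GstD9 (2.65 ± 0.702 against 29 ± 5.49 CPM, adjusted p = 0.000958) and GstD10 (2.59 ± 1.17 against 76.3 ± 21.7 CPM, adjusted p = 0.00108) fell. GstD1 stood at 117 ± 2.28 against 434 ± 135 CPM (adjusted p = 0.00475), and reads may be shared between these paralogs. Of 61 P450 genes, 6 rose, 7 fell and 48 did not pass (8 and 8 adjusted over the list alone). Cyp4p3 (22.8 ± 6.65 against 0.839 ± 0.347 CPM, adjusted p = 0.00157) and Cyp4e3 (1353 ± 507 against 157 ± 55.5 CPM, adjusted p = 0.00183) rose. Cyp9b2 fell (46.2 ± 2.61 against 314 ± 105 CPM, adjusted p = 0.00148), and the P450 list did not pass (camera adjusted p = 0.318). Of 7 pentose phosphate genes, 0 passed singly, while 0 rose and 1 fell adjusted over the list alone. Pentose phosphate genes had a median log2 fold change of -1.06 (camera adjusted p = 0.0175, or 0.63 with an estimated correlation). The tobi call ended without control 0.7 M replicate 1 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.0773). Pentose phosphate genes lost their call without InRi 0.7 M replicate 3 (adjusted p = 0.0637).

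Muscle and cuticle markers lay lower as lists, with 0 genes falling, in the libraries labelled InRi on 0.7 M sucrose. Of 21 muscle genes, 0 passed singly, also adjusted over the list alone. Muscle genes had a median log2 fold change of -0.68 (camera adjusted p = 0.0175, or 0.692 with an estimated correlation). Of 18 cuticle genes, 1 rose, 0 fell and 17 did not pass (1 and 4 adjusted over the list alone). Cuticle genes had a median log2 fold change of -1.05 (camera adjusted p = 0.00468, or 0.47 with an estimated correlation). Of 72 mitochondrial ribosomal protein genes, 0 passed singly, also adjusted over the list alone. They had a median log2 fold change of -0.33 (camera adjusted p = 0.00468, or 0.63 with an estimated correlation). The ecdysone response list did not pass (camera adjusted p = 0.452), although its gene Eip71CD fell (37.2 ± 1.54 against 202 ± 57.2 CPM, log2 fold change -2.45, SE 0.31, adjusted p = 0.00108). Muscle genes lost their call without control 0.7 M replicate 1 or InRi 0.7 M replicate 2 (adjusted p up to 0.263); their median was -0.34 without the latter. Mitochondrial ribosomal proteins lost theirs without control 0.7 M replicate 2 (adjusted p = 0.0968); their median was then -0.20.

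Across all genes 314 rose and 155 fell in the libraries labelled InRi on 0.7 M sucrose, 469 of 8662. Mitochondrial genes took 0.776% to 2.54% of counts in these libraries and 3.39% to 5.39% in control, and 4 non-coding genes 5.53% to 12.6% and 4.11% to 5.07%. Without non-coding and mitochondrial genes 502 passed. At an unadjusted p under 0.05 there were 1622 genes, and DESeq2 called 836. All 469 passed again without control 0.15 M replicate 2, which is in neither group, and 1643 genes were then called (978 higher, 665 lower). The count was 137, 167 and 260 without control 0.7 M replicates 1, 2 and 3. It was 213, 187 and 291 without InRi 0.7 M replicates 1, 2 and 3. Of 33 lists, 12 passed (5 higher, 7 lower) and 0 with an estimated correlation (smallest adjusted p = 0.241).

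Drs, IM2, GstD10, Sodh-1 and Lsp1alpha moved in the same direction on both diets in the libraries labelled InRi. Each genotype came from 1 paternal stock, so the construct is not separated from other differences between the stocks. Of the genes called on each diet 66 were higher on both, where 83 × 314 / 8662 = 3.01 would be expected if independent. Another 40 were lower on both (1.20 expected) and 0 went opposite ways. Across the 8662 genes the log2 fold changes correlated between diets at r = 0.615 (Spearman 0.509, 66.6% of genes with the same sign). Genes are not independent replicates, so r carries no p-value. With 1 library left out r ran from 0.499 (control 0.15 M replicate 3) to 0.652 (control 0.15 M replicate 2).

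**Figure D2:**
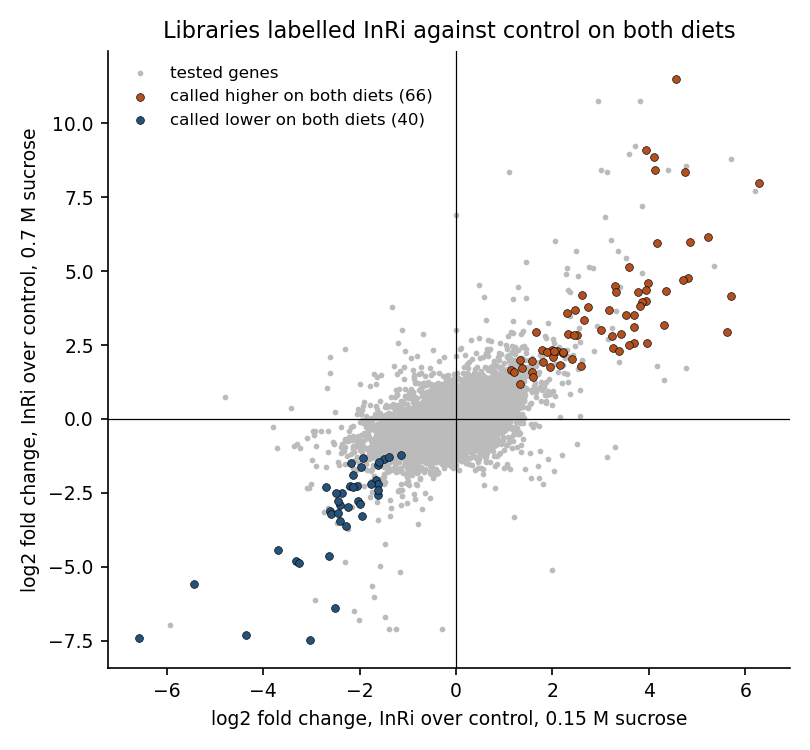
Log2 fold change of libraries labelled InRi against control on 0.15 M (x) and 0.7 M sucrose (y). Coloured points are the 66 genes called higher and the 40 called lower on both diets.

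**Figure D3:**
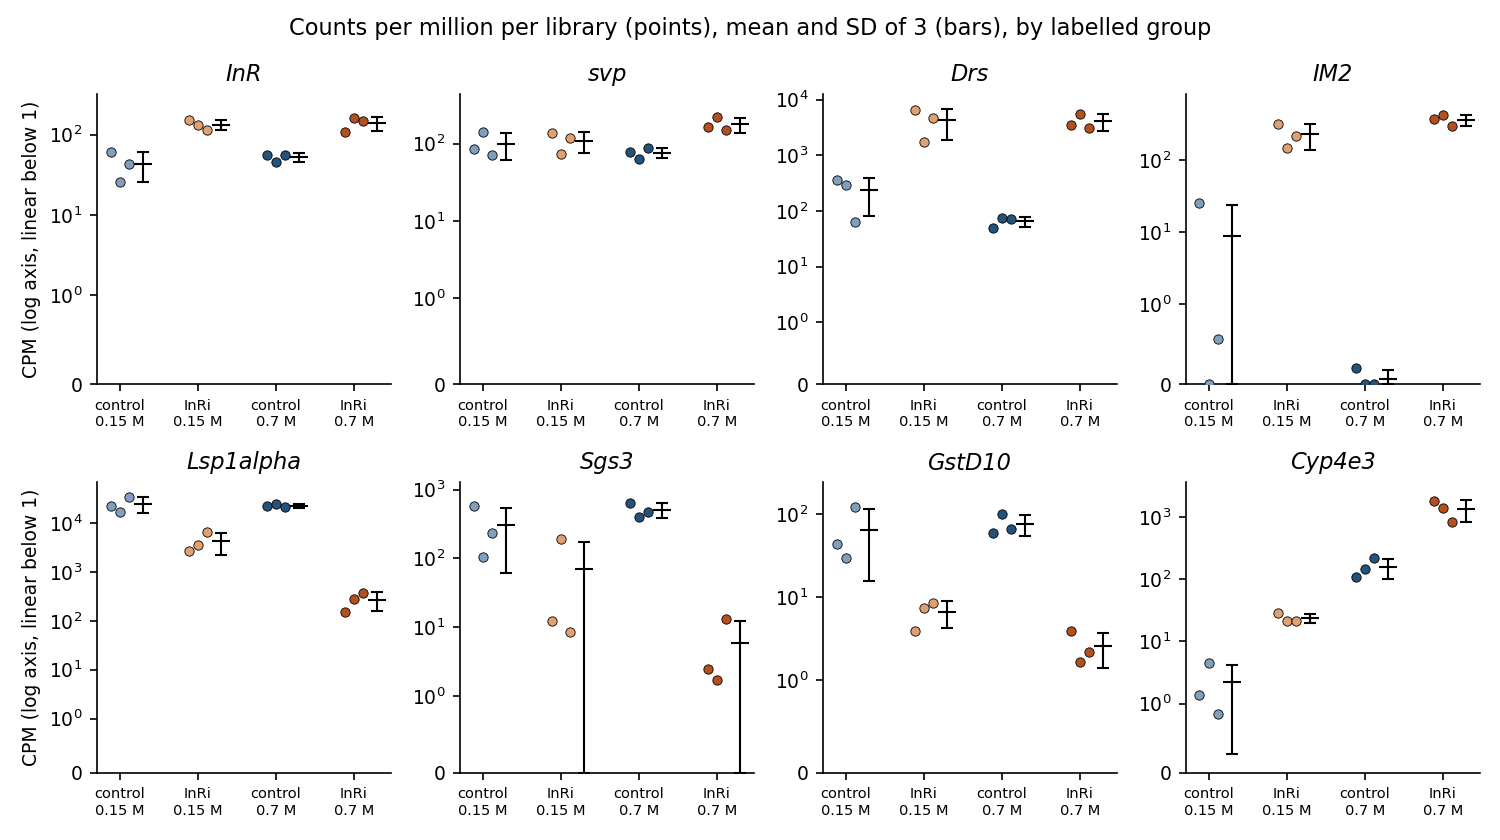
CPM of InR, svp, Drs, IM2, Lsp1alpha, Sgs3, GstD10 and Cyp4e3 in each library (points) with mean ± SD of 3 (bars). The axis is linear below 1 CPM and logarithmic above.

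The P450 gene Cyp4e3 led the rises with 0.7 M sucrose in control larvae, at 157 ± 55.5 against 2.23 ± 1.95 CPM (log2 fold change 6.40, SE 0.57, adjusted p = 0.000558). CG3348 stood at 284 ± 73.7 against 12.3 ± 6.44 CPM (adjusted p = 0.000813) and CG5991 at 51.4 ± 3.13 against 8.01 ± 1.54 CPM (adjusted p = 0.000813). CG13912 (135 ± 41.1 against 29.5 ± 1.76 CPM, adjusted p = 0.00428) and CG1774 (102 ± 26.2 against 15.6 ± 8.85 CPM, adjusted p = 0.0105) rose as well. The nutrient-responsive peptide hormone gene CCHa2 stood at 171 ± 18.7 against 65.7 ± 11.8 CPM (log2 fold change 1.38, SE 0.25, adjusted p = 0.041). The stress gene TotC stood at 55.5 ± 31.8 against 2.92 ± 3.54 CPM (adjusted p = 0.041) and CG43236 at 191 ± 15.1 against 10 ± 11.9 CPM (adjusted p = 0.0212). CG6178 (126 ± 13.6 against 36.8 ± 15.4 CPM, adjusted p = 0.041) and CG12703 (114 ± 26.2 against 40 ± 9.23 CPM, adjusted p = 0.0331) rose less. The calls of Cyp4e3, CG3348, CG5991 and CG13912 held in all 12 omissions of 1 library. CG1774 lost its call without control 0.7 M replicate 2 or 3 (adjusted p up to 0.0887). CG43236 lost its call without control 0.15 M replicate 1, InRi 0.15 M replicate 3 or control 0.7 M replicate 1, 2 or 3 (adjusted p up to 0.0991). TotC, CCHa2 and CG6178 lost theirs in 9, 11 and 10 of 12 omissions (adjusted p up to 0.23, 0.23 and 0.189, without control 0.7 M replicate 2). CG12703 lost its call in 9 of 12 omissions (adjusted p up to 0.134, without control 0.7 M replicate 3).

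Digestive and lysozyme genes were among the largest falls with 0.7 M sucrose in control larvae. CG9672 stood at 1.59 ± 0.679 against 87.6 ± 46.5 CPM (log2 fold change -5.61, SE 0.65, adjusted p = 0.00262) and CG12115 at 7.49 ± 2.34 against 75.3 ± 27.1 CPM (log2 fold change -3.42, SE 0.45, adjusted p = 0.007). CG14850 stood at 3.4 ± 1.99 against 69.9 ± 48.2 CPM (adjusted p = 0.0212). CG13135, with 3 counts left, stood at 0.213 ± 0.222 against 20.7 ± 10 CPM (ratio 67.4, counting interval 22.7 to 330.3, adjusted p = 0.00967). CG3292, also with 3 counts left, stood at 0.213 ± 0.222 against 27.4 ± 18.2 CPM (ratio 101, counting interval 34.1 to 492, adjusted p = 0.041). CG6271, with 1 count left, stood at 0.0738 ± 0.128 against 18.8 ± 12.4 CPM (ratio 216, counting interval 38.2 to 8574, adjusted p = 0.0396). The lysozyme genes LysS (29.3 ± 6.98 against 295 ± 165 CPM, adjusted p = 0.0409) and LysB (3.04 ± 1.21 against 23.6 ± 11 CPM, adjusted p = 0.0331) fell, and reads may be shared between them. Mal-A4, a maltase gene, stood at 4.53 ± 1.74 against 27.9 ± 6.83 CPM (adjusted p = 0.041). Of 38 midgut marker genes, 0 rose, 4 fell and 34 did not pass (1 and 21 adjusted over the list alone). Midgut marker genes had a median log2 fold change of -1.14 (camera adjusted p = 1.02e-13, or 0.452 with an estimated correlation). The CG9672 call ended without control 0.7 M replicate 2 (adjusted p = 0.0586). CG12115 lost its call without control 0.7 M replicate 1 or 2 (adjusted p up to 0.0916). CG14850 lost its call without InRi 0.15 M replicate 3 or control 0.7 M replicate 1, 2 or 3 (adjusted p up to 0.145). CG13135 lost its call without control 0.7 M replicate 1, 2 or 3 (adjusted p up to 0.116). CG3292, LysB and Mal-A4 lost theirs in 8 of 12 omissions, and CG6271 and LysS in 7 (adjusted p up to 0.23 for each, without control 0.7 M replicate 2).

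Fat storage genes lay higher and blood cell genes lower as lists with 0.7 M sucrose in control larvae. Of 16 triglyceride synthesis and lipid droplet genes, 0 passed singly, while 2 rose and 0 fell adjusted over the list alone. Triglyceride genes had a median log2 fold change of 0.41 (camera adjusted p = 0.00379, or 0.528 with an estimated correlation). The lipid droplet gene Lsd-1 stood at 1142 ± 292 against 384 ± 188 CPM (adjusted p = 0.147). Of 19 fatty acid synthesis genes, 0 passed singly, while 2 rose and 1 fell adjusted over the list alone. Fatty acid synthesis had a median log2 fold change of 0.40 (camera adjusted p = 0.00961, or 0.528 with an estimated correlation). The desaturase gene desat1 stood at 742 ± 132 against 242 ± 61.5 CPM (adjusted p = 0.0891). Of 18 hemocyte marker genes, 0 passed singly, while 0 rose and 9 fell adjusted over the list alone. Hemocyte markers had a median log2 fold change of -1.12 (camera adjusted p = 1.76e-06, or 0.0567 with an estimated correlation). nimC1, which encodes a phagocytosis receptor, stood at 9.31 ± 5.18 against 26.4 ± 12.2 CPM (adjusted p = 0.232). Also higher were FOXO targets (median 0.48, camera adjusted p = 0.0309, or 0.608 with an estimated correlation) and P450 genes (median 0.27, camera adjusted p = 0.00871, or 0.716 with an estimated correlation). Lower were heat shock proteins (median -0.36, camera adjusted p = 0.0182, or 0.528 with an estimated correlation). DNA replication genes likewise had -0.11, 0.0372 and 0.584, and trachea and Malpighian tubule markers -0.46, 0.0109 and 0.528. Fatty acid synthesis lost its call without control 0.15 M replicate 1 or control 0.7 M replicate 3 (adjusted p up to 0.0664). FOXO targets lost theirs without control 0.15 M replicate 2 or 3 or control 0.7 M replicate 1 (adjusted p up to 0.146) and P450 genes without control 0.15 M replicate 1 or control 0.7 M replicate 2 (adjusted p up to 0.13). Heat shock proteins lost theirs without control 0.15 M replicate 3 or control 0.7 M replicate 1 (adjusted p up to 0.132). DNA replication lost it in 7 of 12 omissions (adjusted p up to 0.2, without control 0.15 M replicate 1), and trachea markers without control 0.15 M replicate 2 (adjusted p = 0.123). The median without control 0.15 M replicate 2 was -0.74 for hemocyte markers, -0.26 for trachea, 0.12 for P450 genes and -0.31 for DNA replication. Without control 0.15 M replicate 3 it was 0.69 for P450 genes, 0.62 for fatty acid synthesis and -0.24 for DNA replication, which had -0.23 and -0.07 without control 0.7 M replicates 1 and 3.

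Across all genes 11 rose and 13 fell with 0.7 M sucrose in control larvae, 24 of 8662. At an unadjusted p under 0.05 there were 908 genes, and DESeq2 called 180. All 24 passed again without control 0.15 M replicate 2, when 134 genes were called (62 higher, 72 lower). The count was 13 and 8 without InRi 0.15 M replicates 2 and 3, and 12 without InRi 0.7 M replicate 1. It was 6, 4 and 6 without control 0.7 M replicates 1, 2 and 3. With only the 6 control libraries fitted it was 0. Of 33 lists, 9 passed (4 higher, 5 lower), and 0 with an estimated correlation (smallest adjusted p = 0.0567). These counts were 17 and 0 without control 0.15 M replicate 2 (smallest adjusted p = 0.207). The lists added by the preset correlation were glycolysis, sugar storage, pentose phosphate, gluconeogenesis, tricarboxylic acid cycle, lipolysis, cytosolic ribosomal proteins, muscle and cuticle, all higher, and immune effectors, lower.

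Cyp4e3 rose again with 0.7 M sucrose in the libraries labelled InRi, at 1353 ± 507 against 23.7 ± 4.09 CPM (log2 fold change 5.84, SE 0.51, adjusted p = 0.000369), and Cp36 and sad rose too. CG3348 stood at 131 ± 58.7 against 5.38 ± 0.943 CPM (log2 fold change 4.60, SE 0.46, adjusted p = 0.00101). Cp36, a chorion protein gene, stood at 17.1 ± 9.24 against 0.047 ± 0.0815 CPM (1 count on 0.15 M, ratio 316, counting interval 56 to 12530.0, adjusted p = 0.005). sad, which encodes a P450 of ecdysone synthesis, stood at 556 ± 169 against 40.8 ± 38.4 CPM (log2 fold change 3.76, SE 0.60, adjusted p = 0.0114). CG14569 (18.4 ± 7.84 against 0.557 ± 0.22 CPM, adjusted p = 0.005) and CG15553 (36.9 ± 3.17 against 2.64 ± 1.14 CPM, adjusted p = 0.00611) rose as well. CG1077 stood at 409.9 ± 171 against 29.1 ± 14.3 CPM (adjusted p = 0.0121). Cyp4aa1 (5.55 ± 0.849 against 0.243 ± 0.218 CPM, adjusted p = 0.0252) and CG14949 (20.3 ± 6.82 against 1.24 ± 1.74 CPM, adjusted p = 0.021) rose too. CG6074 stood at 15.9 ± 5.78 against 1.23 ± 0.25 CPM (adjusted p = 0.0121). The calls of Cp36 (adjusted p = 0.0508), CG14569 (0.0508) and sad (0.0822) ended without InRi 0.15 M replicate 2. CG15553 lost its call without InRi 0.15 M replicate 2 or 3 (adjusted p up to 0.0624). CG1077 lost its call without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 1 (adjusted p up to 0.0901). Cyp4aa1 lost its call in 6 of 12 omissions (adjusted p up to 0.133, without InRi 0.15 M replicate 2). CG14949 (log2 fold change 3.96, or 6.26 without InRi 0.15 M replicate 1) lost its call without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 1, 2 or 3 (adjusted p up to 0.12). CG6074 lost its call without InRi 0.15 M replicate 1, 2 or 3 or InRi 0.7 M replicate 1 (adjusted p up to 0.0901).

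Lsp1alpha, the larval serum protein gene, fell with 0.7 M sucrose in the libraries labelled InRi (269.6 ± 113 against 4348 ± 2069.8 CPM, log2 fold change -4.01, SE 0.53, adjusted p = 0.005). Obp99a, an odorant-binding protein gene, stood at 40.9 ± 5.25 against 304 ± 94.3 CPM (log2 fold change -2.89, SE 0.49, adjusted p = 0.0143). CG13135 stood at 0.473 ± 0.672 against 39.8 ± 14.7 CPM (adjusted p = 0.00216). CG3292, with 2 counts left, stood at 0.161 ± 0.279 against 26.2 ± 25.6 CPM (ratio 161, counting interval 44.4 to 1336, adjusted p = 0.0121). CG32335 (1.18 ± 0.854 against 18.4 ± 6.86 CPM, adjusted p = 0.00678) and CG9672 (2.56 ± 1.98 against 25.5 ± 11.5 CPM, adjusted p = 0.0156) fell too. CG9021 stood at 2.78 ± 0.877 against 18 ± 1.34 CPM (adjusted p = 0.00768) and CG3819 at 2.51 ± 0.992 against 46.8 ± 29.7 CPM (adjusted p = 0.048). CG14850 (4 ± 1.97 against 34.9 ± 2.86 CPM, adjusted p = 0.0287) and CG15369 (33.9 ± 12.3 against 242 ± 150.1 CPM, adjusted p = 0.0262) also stood lower. Obp99a and CG15369 lost their calls without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 1, 2 or 3 (adjusted p up to 0.101 and 0.154). CG3292 lost its call without InRi 0.15 M replicate 2 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.0922). CG9672 lost its call without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.11). CG9021 lost its call without InRi 0.15 M replicate 2 or InRi 0.7 M replicate 1 (adjusted p up to 0.067). CG3819 and CG14850 lost theirs in 8 and 7 of 12 omissions (adjusted p up to 0.241 and 0.174, without InRi 0.7 M replicate 2).

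Lipid synthesis lay higher as lists, with 2 genes called, with 0.7 M sucrose in the libraries labelled InRi. Of 19 fatty acid synthesis genes, 1 rose, 0 fell and 18 did not pass (8 and 1 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of 0.68 (camera adjusted p = 0.000275, or 0.337 with an estimated correlation). The malic enzyme gene Men, a source of NADPH, stood at 1299 ± 495 against 418 ± 44.2 CPM (log2 fold change 1.63, SE 0.33, adjusted p = 0.0342). Of 16 triglyceride genes, 1 rose, 0 fell and 15 did not pass (1 and 0 adjusted over the list alone). Triglyceride synthesis had a median log2 fold change of 0.61 (camera adjusted p = 0.000558, or 0.337 with an estimated correlation). fu12, an acyltransferase gene, stood at 101 ± 35.7 against 16.8 ± 4.06 CPM (log2 fold change 2.59, SE 0.45, adjusted p = 0.017). Of 31 immune effector genes, 1 rose, 0 fell and 30 did not pass (3 and 0 adjusted over the list alone). Immune genes had a median log2 fold change of 0.56 (camera adjusted p = 0.000275, or 0.408 with an estimated correlation). DptB, an antibacterial peptide gene, stood at 13.6 ± 4.34 against 2.28 ± 0.282 CPM (log2 fold change 2.56, SE 0.42, adjusted p = 0.0121). Also higher were lipolysis and fatty acid oxidation genes (median 0.28, camera adjusted p = 0.013, or 0.457 with an estimated correlation) and FOXO targets (median 0.54, camera adjusted p = 0.00326, or 0.408 with an estimated correlation). So were P450 genes (median 0.30, camera adjusted p = 0.00393, or 0.457 with an estimated correlation) and endoplasmic reticulum chaperones (median 0.36, camera adjusted p = 0.00135, or 0.436 with an estimated correlation). Smaller were the shifts of insulin and Tor signalling (median 0.22, camera adjusted p = 0.0327, or 0.457 with an estimated correlation) and cytosolic ribosomal proteins (median 0.16, camera adjusted p = 0.0268, or 0.503 with an estimated correlation). So was that of autophagy (median 0.16, camera adjusted p = 0.0296, or 0.408 with an estimated correlation). Men lost its call in 8 of 12 omissions (adjusted p up to 0.199, without InRi 0.15 M replicate 2). fu12 lost its call without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 1 (adjusted p up to 0.12) and DptB without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 2 (adjusted p up to 0.103). Lipolysis lost its call without InRi 0.15 M replicate 2 (adjusted p = 0.0589), and insulin signalling without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 2 (adjusted p up to 0.138). Ribosomal proteins lost theirs without InRi 0.15 M replicate 2 (adjusted p = 0.184), and autophagy without InRi 0.15 M replicate 2 or InRi 0.7 M replicate 2 (adjusted p up to 0.14). Without InRi 0.15 M replicate 2 the median was 0.07 for ribosomal proteins, 0.19 for lipolysis (0.50 without replicate 3), 0.32 for FOXO targets and 0.18 for P450 genes. Without InRi 0.7 M replicate 1 it was 0.17 for P450 genes and 0.44 for fatty acid synthesis, and without replicate 2 0.32 for FOXO targets.

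Lists of ribosome biogenesis, DNA replication and markers of other tissues were lower with 0.7 M sucrose in the libraries labelled InRi. These included ribosome biogenesis (median -0.46, camera adjusted p = 0.00517, or 0.337 with an estimated correlation) and DNA replication (median -0.48, camera adjusted p = 0.000275, or 0.337 with an estimated correlation), with 0 of 25 and 0 of 31 genes called. Of 9 salivary gland marker genes, 0 passed singly, while 0 rose and 6 fell adjusted over the list alone. Glue genes had a median log2 fold change of -3.42 (camera adjusted p = 0.00135, or 0.408 with an estimated correlation). The median was the same with genes at 0 counts set to their bounds. Without InRi 0.15 M replicate 2, high in these genes, it was -0.89 (camera adjusted p = 0.0351). Of 38 midgut marker genes, 1 rose, 3 fell and 34 did not pass (4 and 7 adjusted over the list alone). Midgut genes had a median log2 fold change of -0.50 (camera adjusted p = 0.00196, or 0.457 with an estimated correlation). LysC stood at 6.91 ± 1.9 against 31.3 ± 9.95 CPM (log2 fold change -2.19, SE 0.37, adjusted p = 0.0143). Lower too were cuticle genes (median -0.65, camera adjusted p = 0.00141, or 0.337 with an estimated correlation). In that order, imaginal disc genes had -0.58, 0.0216 and 0.457, hemocyte markers -0.70, 0.0418 and 0.35, and trachea markers -0.39, 0.0268 and 0.436. Heat shock proteins likewise had -0.22, 0.0134 and 0.337, and the ecdysone response -0.22, 0.0411 and 0.337. LysC lost its call without InRi 0.15 M replicate 2 or 3 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.106), and the midgut list without InRi 0.7 M replicate 2 (adjusted p = 0.126). Disc genes lost their call without InRi 0.15 M replicate 1 or 2 or InRi 0.7 M replicate 2 (adjusted p up to 0.092). Hemocyte markers lost theirs without InRi 0.15 M replicate 2, control 0.7 M replicate 1 or InRi 0.7 M replicate 1 or 2 (adjusted p up to 0.108), and trachea markers without InRi 0.15 M replicate 2 or InRi 0.7 M replicate 1 (adjusted p up to 0.16). Heat shock genes lost theirs without InRi 0.15 M replicate 3 or InRi 0.7 M replicate 1 (adjusted p up to 0.0654), and the ecdysone response without InRi 0.15 M replicate 1 or InRi 0.7 M replicate 1 or 3 (adjusted p up to 0.141). The heat shock median was -0.01 without InRi 0.15 M replicate 3, and -0.06, -0.34 and 0.02 without InRi 0.7 M replicates 1, 2 and 3. The midgut median was -0.75 without InRi 0.15 M replicate 1, and -0.28 and -0.97 without InRi 0.7 M replicates 2 and 3. For cuticle it was -1.04 and -0.42 without InRi 0.15 M replicates 1 and 2, and -1.64 without InRi 0.7 M replicate 1. Without InRi 0.15 M replicate 2 it was -0.24 for trachea and -0.38 for disc genes, which had -0.35 without InRi 0.7 M replicate 2.

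Across all genes 88 rose and 21 fell with 0.7 M sucrose in the libraries labelled InRi, 109 of 8662. At an unadjusted p under 0.05 there were 987 genes, and DESeq2 called 312. All 109 passed again without control 0.15 M replicate 2, which is in neither group, when 594 genes were called (408 higher, 186 lower). The count was 72, 7 and 18 without InRi 0.15 M replicates 1, 2 and 3. It was 23, 27 and 54 without InRi 0.7 M replicates 1, 2 and 3, and 68 without control 0.7 M replicate 3. Of 33 lists, 20 passed (10 higher, 10 lower) and 0 with an estimated correlation (smallest adjusted p = 0.337).

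Cyp4e3, CG3348, CG13135, CG3292, CG9672 and CG14850 moved in the same direction with sucrose in both genotypes. Of the genes called in each, 9 were higher in both, where 11 × 88 / 8662 = 0.112 would be expected if independent. Another 6 were lower in both (0.0315 expected) and 0 went opposite ways. Across 8662 genes the sucrose effects correlated between genotypes at r = 0.358 (Spearman 0.291, 59.5% with the same sign). With 1 library left out this r ran from 0.272 (control 0.15 M replicate 3) to 0.374 (control 0.15 M replicate 2). The average effect of the label InRi and the average effect of sucrose gave r = 0.357 (Spearman 0.505), which the spread between libraries alone can produce. In 500 simulated sets of unchanged groups the log2 CPM correlation averaged 0.354 (95% of sets from -0.639 to 0.952), against 0.464 observed. The covariance was 0.205 against 0.0852 simulated. Without control 0.7 M replicate 1 that r was 0.264, and without control 0.15 M replicate 1 it was 0.505.

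Midgut, salivary gland and immune genes shared the smallest camera adjusted p of the lists for the interaction of diet and genotype, which none passed with an estimated correlation. In edgeR 0 of 8662 single genes passed. At an unadjusted p under 0.05 there were 456 genes, DESeq2 called 17, and the smallest adjusted p in edgeR was 0.339. Higher in the interaction were immune effectors (median 1.03, camera adjusted p = 2.28e-05, or 0.634 with an estimated correlation) and midgut markers (median 0.69, camera adjusted p = 2.28e-05, or 0.746 with an estimated correlation). The same held for endoplasmic reticulum chaperones (median 0.43, camera adjusted p = 0.00268, or 0.812 with an estimated correlation) and hemocyte markers (median 0.49, camera adjusted p = 0.0149, or 0.384 with an estimated correlation). Lower were salivary gland markers (median -4.32, camera adjusted p = 2.28e-05, or 0.585 with an estimated correlation) and cuticle genes (median -0.83, camera adjusted p = 0.00061, or 0.384 with an estimated correlation). Lower too was ribosome biogenesis (median -0.50, camera adjusted p = 0.00107, or 0.384 with an estimated correlation). Also higher was the tricarboxylic acid cycle (median 0.42, camera adjusted p = 0.04, or 0.819 with an estimated correlation). That call ended in 6 of 12 omissions (adjusted p up to 0.918, without control 0.15 M replicate 2), where the direction also turned. Its median ran from 0.01 without that library to 0.63 without replicate 1, and was 0.25 and 0.15 without InRi 0.15 M or InRi 0.7 M replicate 1. Chaperones lost theirs without InRi 0.15 M replicate 2 (adjusted p = 0.0671), and hemocyte markers without control 0.15 M replicate 3 or InRi 0.7 M replicate 3 (adjusted p up to 0.0703). Without InRi 0.15 M replicate 2 the median was -1.63 for salivary gland and 1.11 for midgut markers, which had 0.39 without InRi 0.7 M replicate 3. It was 0.81 and 0.30 for hemocyte markers without control 0.15 M replicates 1 and 2. Without control 0.7 M replicate 2 it was -0.29 for ribosome biogenesis and 0.66 for chaperones. Cuticle genes had -0.54 without control 0.15 M replicate 1 and -1.29 without InRi 0.7 M replicate 1. Of 33 lists 8 passed (5 higher, 3 lower), 14 without control 0.15 M replicate 1, and 0 with an estimated correlation (smallest adjusted p = 0.384). The gene count was 0 to 2 in all omissions of 1 library.

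**Figure D4:**
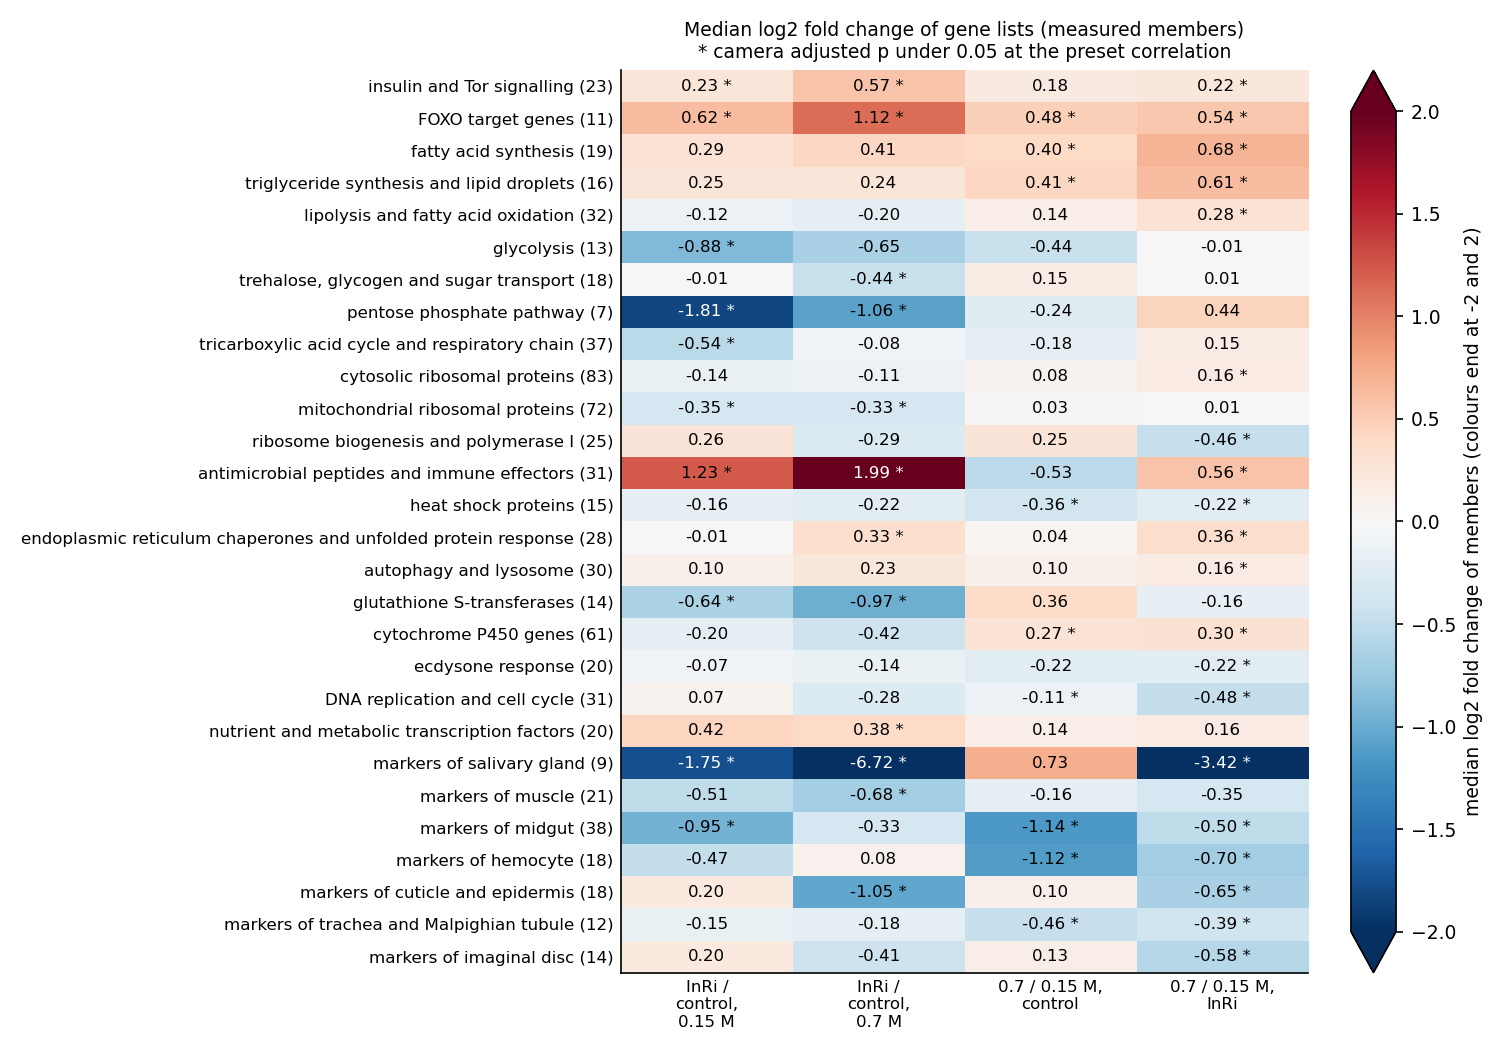
Median log2 fold change of 28 gene lists in the 4 pairwise comparisons. Asterisks mark camera adjusted p under 0.05 with the preset correlation.

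Fat body secreted signals passed as a list in none of the comparisons, although Ilp6 and egr passed as single genes on both diets in the libraries labelled InRi. Their camera adjusted p in pairwise comparisons was 0.208, 0.417, 0.232 and 0.293. With all 12 libraries the larval serum, gluconeogenesis, nervous system and germline lists did not pass in these 4 either (camera adjusted p from 0.105 to 0.967).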

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

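The tests below on transcript length, other tissue and muscle, FOXO targets, exchanged labels, sage and ecdysone genes were chosen after the result was seen, while those on read number, the hairpin and the splits were set before.

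Immune, salivary gland and midgut genes each had adjusted p = 2.28e-05 for the interaction of diet and genotype by camera, but 0.634, 0.585 and 0.746 with an estimated correlation. The same test gave adjusted p = 0.00061 for cuticle genes, 0.00107 for ribosome biogenesis, 0.00268 for endoplasmic reticulum chaperones, 0.0149 for hemocyte markers and 0.0400 for the tricarboxylic acid cycle. With an estimated correlation none of these passed either (smallest adjusted p = 0.384). Without control 0.15 M replicate 2 the tricarboxylic acid cycle had adjusted p = 0.918 and the opposite direction.

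CG5171, listed among the sugar storage genes, was at 29.7 ± 8.38 CPM in the libraries labelled InRi and 18.9 ± 1.32 in control on 0.15 M sucrose. On 0.7 M sucrose it was at 16.0 ± 2.17 and 31.7 ± 6.04 CPM, n = 3. All libraries of each pair of groups went the opposite way on the other diet, and with sucrose in the other genotype (interaction log2 -1.66, edgeR adjusted p = 0.484). CG6839 was at 3.93 ± 1.17 CPM in the libraries labelled InRi and 23.7 ± 18.4 in control on 0.15 M sucrose, and at 7.70 ± 4.37 and 1.63 ± 0.565 CPM on 0.7 M (interaction log2 4.70, edgeR adjusted p = 0.339). CG5171 passed between genotypes on 0.7 M (adjusted p = 0.0423), and CG6839 on 0.15 M (0.0390) and with sucrose in control (0.0428). The interaction passed for neither gene, so a difference between these effects was not shown.

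Mitochondrial transcripts were 101-fold lower in control 0.15 M replicate 2 than in the other libraries of its group, which is a log2 ratio of -6.66, and many other genes stood apart. Dilution by RNA of another tissue is argued against for the mitochondrial transcripts alone, because the larval serum list kept a median log2 ratio of -0.04 (SD over genes 1.98). RNA of muscle stays open for the other genes, with a median log2 ratio of 1.47 (17 muscle genes higher, 4 lower), beside 2.24 for pentose phosphate, 1.42 for glycolysis, -1.60 for germline and -1.79 for salivary gland markers. Loss of long transcripts is argued against by a Spearman rho with exonic length of 0.111 (other libraries -0.394 to 0.342). The shortest 1704 genes had a median log2 ratio of -1.10, longer ones -0.401 to -0.226. Low read number is argued against, because the other 2 libraries of the group thinned to its total kept a mean rho of at least 0.906, against 0.732 in this library. RNA quality, which that may reflect, and the day of preparation stay open.

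InR was higher where the construct should lower it, with a log2 fold change of 1.60 on 0.15 M and 1.42 on 0.7 M sucrose (lowest with 1 library left out 1.33 and 1.31). Higher transcription as a FOXO target is a candidate. The other 10 FOXO targets lay higher as a list on both diets (larger unadjusted camera p = 0.00477, n = 12 libraries). Among them NLaz fell on 0.7 M. With an estimated correlation the larger p was 0.138, so neither FOXO nor exchanged genotype labels are decided. Reads of the hairpin transcript counted to InR stay open as well, because counts per gene hold no read positions.

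Salivary gland genes were lower in the libraries labelled InRi on 0.7 M sucrose, Sgs7 at 18.0 CPM against 1866 in control. Less salivary gland in the fat body preparation is a candidate explanation. sage, a salivary gland factor gene outside the list, fell by 3.21 on the log2 scale (edgeR adjusted p = 0.00108) against a list median of -6.72. It also fell on 0.15 M (-2.59, adjusted p = 0.00522), to 2.12 to 3.47 CPM, where glue genes of InRi 0.15 M replicate 2 stood near control (mean log2 CPM 5.49, control 4.77 to 6.63). So sage did not follow the glue genes in that library and does not decide this. A stage difference stays open. The ecdysone list had no common shift on 0.7 M (unadjusted camera p = 0.315, n = 12 libraries). Cyp18a1 rose (log2 3.19) and Eip71CD fell (-2.45).

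Of the 10 splits of the 6 libraries of each pairwise comparison, only 1, the real one, gave as many genes (150, 469, 24 and 109), and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached. For the interaction the comparison is empty, since all 100 splits drawn must give at least the 0 genes of the real one. The highest, 237 genes, set control 0.15 M replicate 1 with InRi 0.15 M replicates 1 and 3 and all control 0.7 M libraries. The next, 51 genes, exchanged all genotypes on 0.7 M and mostly kept those on 0.15 M. In both the genotype difference enters the interaction. Other splits that left the 0.7 M groups whole gave 0 or 1.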

How the results depend on the processing

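The alternatives with sample quality weights (voom) and without non-coding genes, and the singling out of control 0.15 M replicate 2, were chosen after the data were examined. Counts of genes are given in the order InRi on 0.15 M, InRi on 0.7 M, sucrose in control, sucrose in InRi, interaction (150, 469, 24, 109 and 0 in edgeR). Alternatives for FPKM values did not apply.

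DESeq2 called 560, 836, 180, 312 and 17 genes, and voom 541, 1587, 132, 614 and 4. At a threshold of 0.01 there were 40, 170, 7 and 19. With only the groups compared in the fit there were 0, 1700, 0 and 343, and InR kept its log2 fold change of 1.60 on 0.15 M sucrose but lost its call (adjusted p = 0.295). With no filter sucrose in control gave 58. With the replicate number as a block the counts were 305 for InRi on 0.7 M, 11 for sucrose in control and 53 for sucrose in InRi. The numbers do not pair the libraries: residuals of same-number pairs had a median r of -0.0235, and 1 of 12 libraries fitted best with its own number.

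Leaving out 1 library moved the counts over 43 to 383, 137 to 1643, 4 to 134, 7 to 594 and 0 to 2. The highest pairwise counts all came without control 0.15 M replicate 2. InR ran from 1.33 to 1.90 on 0.15 M and from 1.31 to 1.58 on 0.7 M sucrose, and its call ended in 2 and 5 of 12 omissions. Of 159 calls of named genes, 127 ended under at least 1 alternative, and 0 changed direction.

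Lists past the threshold numbered 0 in all comparisons with an estimated correlation. Leaving out 1 library gave 6 to 17 lists for sucrose in control (16 with voom) and 7 to 14 for the interaction. The tricarboxylic acid cycle list turned in the interaction without control 0.15 M replicate 2 (adjusted p = 0.918, and 0.000232 without replicate 1 of that group).

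The correlation between diets was 0.333 with no filter, 0.686 with voom and 0.499 to 0.652 with 1 library left out. Between genotypes it was 0.148, 0.396 and 0.272 to 0.374. For the averaged effects it was 0.273 with no filter and 0.264 to 0.505 with 1 library left out.

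Values that did not pass turned in sign. svp on 0.15 M sucrose was -0.031 without control 0.15 M replicate 3 and ran from -0.043 (without InRi 0.15 M replicate 1) to 0.47 with 1 library left out. InR ran from -0.019 (without control 0.15 M replicate 2) to 0.55 for sucrose in control, and from -0.46 to 0.11 (without that library) in the interaction. For sucrose in InRi it ran from -0.039 (without InRi 0.7 M replicate 2) to 0.23, and was -0.014 without InRi 0.15 M replicate 3.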

Other observations

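Turandot genes besides those named, the ecdysone synthesis gene sad and the chorion gene Cp36 were looked at after their values were seen. TotA was the most abundant Turandot gene, at 3313 ± 1722 CPM in the libraries labelled InRi and 540.4 ± 396 in control on 0.15 M sucrose, n = 3 (edgeR adjusted p = 0.0702). On 0.7 M sucrose it was at 5715 ± 269.6 and 1443 ± 629 CPM (edgeR adjusted p = 0.108). Without control 0.15 M replicate 2 TotA passed on both diets (adjusted p = 0.0131 and 0.00189). TotC and Victoria rose on 0.7 M sucrose too (log2 fold change 2.94 and 4.17, edgeR adjusted p = 0.0173 and 0.0174), while TotB had 1.71 (adjusted p = 0.134, or 0.0253 without that library).

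sad was at 556 ± 169 CPM only in the libraries labelled InRi on 0.7 M sucrose, against 27.3 ± 6.43, 40.8 ± 38.4 and 32.1 ± 10.3 CPM in the other groups (edgeR adjusted p = 0.00224 against control on that diet). Cp36 was at 17.1 ± 9.24 CPM there, against 1.02 ± 0.79 in control on 0.7 M sucrose (edgeR adjusted p = 0.00917) and 0 in control on 0.15 M. Without control 0.7 M replicate 1 the Cp36 adjusted p was 0.059. The interaction did not pass for sad (adjusted p = 0.484) or Cp36 (0.988), so a sucrose effect that differs between genotypes was not shown.

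Dcr-2, which mothers of both crosses carried as a transgene, ran from 858 to 15060.0 CPM between libraries (log2 fold change 1.33 and 1.44 on the 2 diets, edgeR adjusted p = 0.259 and 0.221, or 0.268 and 0.0103 without control 0.15 M replicate 2). Obp99a had an interaction of -2.40 (edgeR adjusted p = 0.845), and without control 0.15 M replicate 2 it was the 1 gene that passed (-3.26, adjusted p = 0.0117). The storage genes Lsp1beta and Lsp2 did not pass where Lsp1alpha fell, with log2 fold changes of -0.52 and 0.71 on 0.7 M sucrose (edgeR adjusted p = 0.619 and 0.5).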
